A study of Arabidopsis thaliana with 9 samples.

How the data were processed

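Gene expression was measured by RNA sequencing of whole 6-day-old Arabidopsis seedlings, 3 libraries each of the wild type, green 2cpab and albino 2cpab. Per the submitters' processing notes, RNA was extracted with a SurePrep kit and libraries were made from poly(A) RNA with a stranded Illumina mRNA ligation kit. The notes name FastQC, HISAT2 and StringTie without versions and the TAIR10 genome. The authors deposited log2 values, 1 table of 32833 genes in 9 libraries, and these deposited log2 values were used as they are.

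The unit was read from the values. The deposited log2 values are log2 of FPKM times a factor plus 1, and every library has the same 75th percentile, 3.70. When the scaling is undone, 84.3% to 87.2% of values per library fall on a grid of 6 decimals, against 18.3% to 21.4% if it had been made after the log. The factor was 1.05 ± 0.0528 in the wild type, 1.04 ± 0.0848 in green and 0.787 ± 0.00551 in albino libraries (mean and SD, n = 3 each). The plan had taken the values for FPKM to be logged with a pseudocount of 1; since the authors had already done this, no further transformation was made. Absolute depth is unknown, as read counts were not used here. Gene names and positions came from the TAIR10.1 annotation, which matched 32548 genes. The 285 others are organelle codes, 133 of the plastid and 152 of mitochondria. All libraries held 0 for 6331 genes.

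Genes with scaled FPKM of at least 1 in at least 3 libraries were tested, 19731 in all. The fit was limma on the log2 values with a mean per group over all 9 libraries and moderated variances with a trend. P values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at adjusted p < 0.05. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 32 lists of a comparison. The lists hold 497 members, 492 different genes, and were written from general knowledge before the data were examined. Shares of FPKM were compared with exact two-sided permutation tests. Software was R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

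Genes were named by a rule set before the data were examined. It takes 2CPA, 2CPB, cpHSC70-1 and cpHSC70-2. It adds the 8 largest rises and 8 largest falls per comparison among called genes whose groups do not overlap and whose higher mean is at least 5. From each list it takes up to 3 called members with the largest change, or else up to 2 with the largest mean. Genes outside the rule are said to have been chosen after their values were seen.

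The code was tested on simulated data, drawn from the real gene means and spread, with 50 genes per mutant group changed at each of 4 folds. Changed genes came only from those with a wild-type mean log2 value above 2, and noise was independent between genes and libraries. The shares called therefore do not cover weaker genes or shifts shared by many genes of a library. In green against wild-type libraries 96%, 82%, 78% and 94% of genes at 0.25, 0.5, 2 and 4 fold were called, with 5 false calls. In albino against wild-type libraries the shares were 96%, 70%, 84% and 98%, with 9 false calls.

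Alternatives set before the data were examined changed the pseudocount (0.1 or 5), the filter (none or stricter), the scaling (TPM, median of ratios, quantile, or a common sum without organelle genes), the fit (only the 6 libraries compared, no trend, robust, replicate block), a required 2-fold change, the list test (estimated correlation or fry) and each library left out in turn. Chosen after seeing the data were the undone scaling, the removal of genes listed at 0 in part of a group, and the removal of both green replicates 2 and 3. The lists of iron, copper and touch genes were also added after seeing the data. Reads, splicing, sequence variants and protein levels were not analysed here.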

Results

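Poly(A) RNA of 6-day-old Arabidopsis thaliana seedlings was sequenced in 9 libraries. The seedlings had grown in continuous light of 125 µE m-2 s-1 on MS medium containing 0.5% sucrose. Each of 3 groups held 3 libraries: the wild type (Col-0), green seedlings of the 2cpab mutant and albino seedlings of the same mutant. The mutant is named for 2CPA and 2CPB, the nuclear genes of the chloroplast 2-Cys peroxiredoxins, thiol enzymes that reduce hydrogen peroxide with electrons from thioredoxin-type reductants. The series title joins these enzymes to cpHSP70, the HSP70 chaperone of the chloroplast stroma, in the building of chloroplasts. The comparison of green mutants with the wild type asks which transcripts differ in mutants that still green. The comparison of albino mutants with the wild type asks which differ in mutants without green pigment. The comparison of both mutant groups asks which transcripts differ between green and albino mutants. These groups differ in 2CPA and 2CPB RNA as well as in pigment, and the comparison cannot tell these apart. The deposited values are log2 of scaled FPKM plus 1, with the same 75th percentile in every library, and levels are given here as scaled FPKM with the SD over 3 libraries. Log2 fold changes are on the log2(scaled FPKM + 1) scale, which understates changes of weakly expressed genes, and are followed by their standard error. Total read counts were not used here, so absolute depth is unknown; relative depth, read from ratios of low FPKM values, lay between 0.868 and 1.15 of that of wild-type replicate 1. Between 22926 and 23963 genes per library were above 0, and 19731 genes were tested with limma. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

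RNA of both targeted genes was lower in every mutant library than in any wild-type library. 2CPA (AT3G11630, a protein-coding gene on chromosome 3 from 3672036 to 3674159 in the TAIR10.1 annotation) stood at 989, 763 and 889.7 in the wild-type replicates 1 to 3. It was at 35.8, 267 and 256 in the green replicates and at 24.2, 21.4 and 25.4 in the albino replicates. The second gene, 2CPB (AT5G06290, protein coding, chromosome 5 from 1919080 to 1921425), stood at 237, 174 and 188 in the wild type, 7.21, 48.6 and 54.2 in green and 1.82, 2.89 and 1.52 in albino seedlings. Against the wild type, the log2 fold change of 2CPA was -2.68 ± 0.62 (adjusted p = 0.0259) in green and -5.16 ± 0.62 (adjusted p = 0.000127) in albino seedlings, and that of 2CPB was -2.82 ± 0.60 (adjusted p = 0.0179) and -6.04 ± 0.60 (adjusted p = 3.82e-05). Both genes were also lower in albino than in green seedlings, 2CPA by 2.47 ± 0.62 (adjusted p = 0.0115) and 2CPB by 3.22 ± 0.60 (adjusted p = 0.00231). Green replicate 1 stood apart from the other green libraries, with 4.07% of the wild-type mean of 2CPA against 30.3% and 29.1% in green replicates 2 and 3, and 3.6% of the wild-type mean of 2CPB against 24.3% and 27.1%. The list of both genes was lower as a set in green (camera adjusted p = 0.0179, adjusted p = 0.593 with an estimated correlation) and in albino seedlings (0.0169, adjusted p = 0.255 with an estimated correlation), with 2 of 2 genes lower in each comparison also when adjusted over the list alone. Between the mutant groups the set did not pass (camera adjusted p = 0.0613; 0.000836 without green replicate 1, 0.00506 under TPM, 0.00455 with organelle genes removed, 0.00774 with the scaling undone, 0.0129 with fry and 0.0243 without green replicates 2 and 3). The calls in green were fragile: that of 2CPA was lost without wild-type replicate 1 (adjusted p = 0.0693), 2 (0.0507) or 3 (0.0752), and that of 2CPB without wild-type replicate 1 (0.0541) or 3 (0.0541). With only the 6 libraries compared both were lost (0.0709 and 0.0502), and 2CPA also without a filter (0.0594) or with a robust fit (0.0544). The ranges over all alternatives were 8.56e-05 to 0.0752 and 0.000641 to 0.0541. With green replicate 1 as the only green library, an alternative chosen after seeing the data in which the lone library is taken to vary like the others, 2CPA no longer passed between albino and green (-0.58, adjusted p = 0.0654).

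RNA of both stromal HSP70 genes was lower in albino than in green seedlings, and that of cpHSC70-2 was also lower than in the wild type. The gene cpHSC70-1 (AT4G24280, protein coding, chromosome 4 from 12589810 to 12593800) was at 175 ± 8.58 in the wild type, 228 ± 50.3 in green and 134 ± 12.3 in albino seedlings (n = 3 each). Its relative cpHSC70-2 (AT5G49910, protein coding, chromosome 5 from 20303334 to 20306469) was at 126 ± 7.73, 157 ± 41.8 and 65.6 ± 10.1. Both encode chaperones that fold and import proteins in the stroma. Neither passed in green seedlings against the wild type, with 0.35 ± 0.16 (adjusted p = 0.229) for cpHSC70-1 and 0.28 ± 0.19 (adjusted p = 0.459) for cpHSC70-2. In albino seedlings cpHSC70-2 fell by 0.94 ± 0.19 (adjusted p = 0.00335) on the log2 scale, whereas cpHSC70-1 had -0.38 ± 0.16 (adjusted p = 0.0759). Between albino and green seedlings, cpHSC70-1 fell by 0.74 ± 0.16 (adjusted p = 0.00528) and cpHSC70-2 by 1.22 ± 0.19 (adjusted p = 0.000952). Adjusted over the list alone, 2 of 2 genes were lower in albino seedlings than in the wild type and 2 of 2 than in green ones, and 0 differed in green seedlings. As a set they passed only between albino and green (camera adjusted p = 0.0421, adjusted p = 0.272 with an estimated correlation), not against the wild type (green 0.282, albino 0.135, 0.0250 with fry). That call was lost without wild-type replicates 1 or 2, green replicate 3 or albino replicate 3 (adjusted p from 0.0104 to 0.0552 over the 9 libraries left out in turn). It was also lost with the stricter filter (0.0674), with quantile normalization (0.0849), with only the 6 libraries compared (0.0669), with the replicate block (0.0513) and without green replicates 2 and 3. The results for cpHSC70-1 rest on few libraries. Without green replicate 1 it was higher in green seedlings than in the wild type (0.55, adjusted p = 0.0218, over alternatives 0.0218 to 0.947), the set then passed in green (0.0267), and it was lower in albino seedlings (adjusted p = 0.0136, over alternatives 0.0136 to 0.899). It also passed there with only the 6 libraries compared (0.0185), with median-of-ratios scaling (0.0481) and without green replicates 2 and 3 (0.0187). Its value in albino seedlings turned to 0.08 under TPM, to 0.09 with organelle genes removed and to 0.03 with the scaling undone. Its difference between the mutant groups no longer passed under TPM (-0.29, adjusted p = 0.0504) or with organelle genes removed (-0.28, adjusted p = 0.0505). Without green replicates 2 and 3 its values were -0.03 in green against the wild type and -0.35 (adjusted p = 0.163) between the mutant groups. In green seedlings cpHSC70-2 then turned to -0.20.

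**Figure D1:**
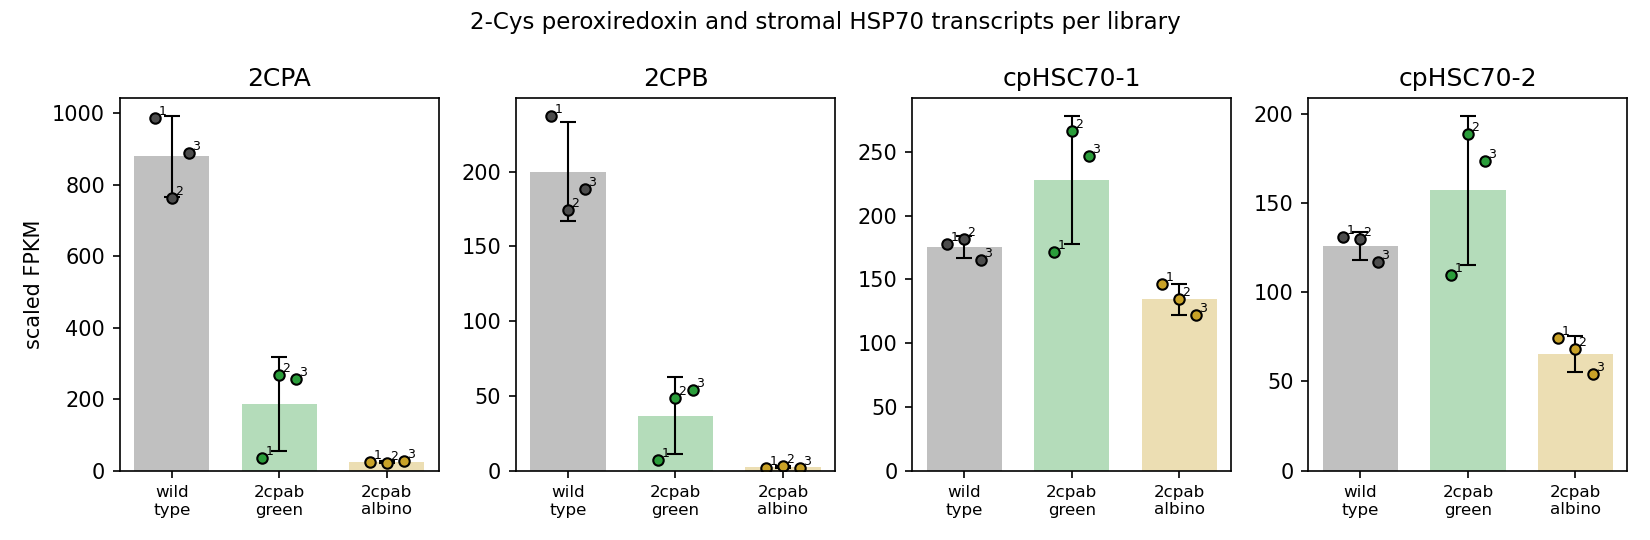
Scaled FPKM (vertical axes, each starting at 0) of 2CPA, 2CPB, cpHSC70-1 and cpHSC70-2 in each of the 9 libraries (points), with the group mean and SD of 3 libraries. 2CPA spans 763 to 989 in the wild type, 35.8 to 267 in green and 21.4 to 25.4 in albino seedlings.

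Green mutant seedlings held far more RNA of heat-shock proteins than the wild type. Of 21 measured heat-shock genes that act outside the plastid, 20 rose and 0 fell (20 also adjusted over the list alone), with a median log2 fold change of 3.88. The small heat-shock proteins, chaperones that bind unfolding proteins, led: HSP22 of the endomembrane system rose from 0.741 ± 0.404 to 79.9 ± 41.5 (5.39 ± 0.60, adjusted p = 0.000936). HSP15.7 rose by 5.26 ± 0.58 (adjusted p = 0.000901), cytosolic HSP17.6C by 5.04 ± 0.73 (adjusted p = 0.00318) and mitochondrial HSP23.6 by 4.80 ± 0.57 (adjusted p = 0.00125). HSP17.6II, HSP17.6A and the small heat-shock protein genes AT1G52560 and AT2G29500 were also among the 8 largest rises in this comparison, by 4.66, 4.62, 4.68 and 4.54. The member that did not pass, the cytosolic chaperone HSC70-1, named after its value was seen, had 0.31 ± 0.17 (adjusted p = 0.326). The set passed against all other genes (camera adjusted p = 2.87e-22; adjusted p = 0.593 with an estimated correlation, and 0.0137 with fry, which tests only whether the genes move one way). The list median over the wild-type mean was 2.72 in green replicate 1, 4.04 in replicate 2 and 4.37 in replicate 3, against -0.42 to 0.34 in the wild-type libraries. Green replicate 1, which also held the least 2CPA and 2CPB RNA, thus had the smallest rise. Of the members, 20 passed without it and 8 with it as the only green library (the latter chosen after seeing the data).

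**Figure D2:**
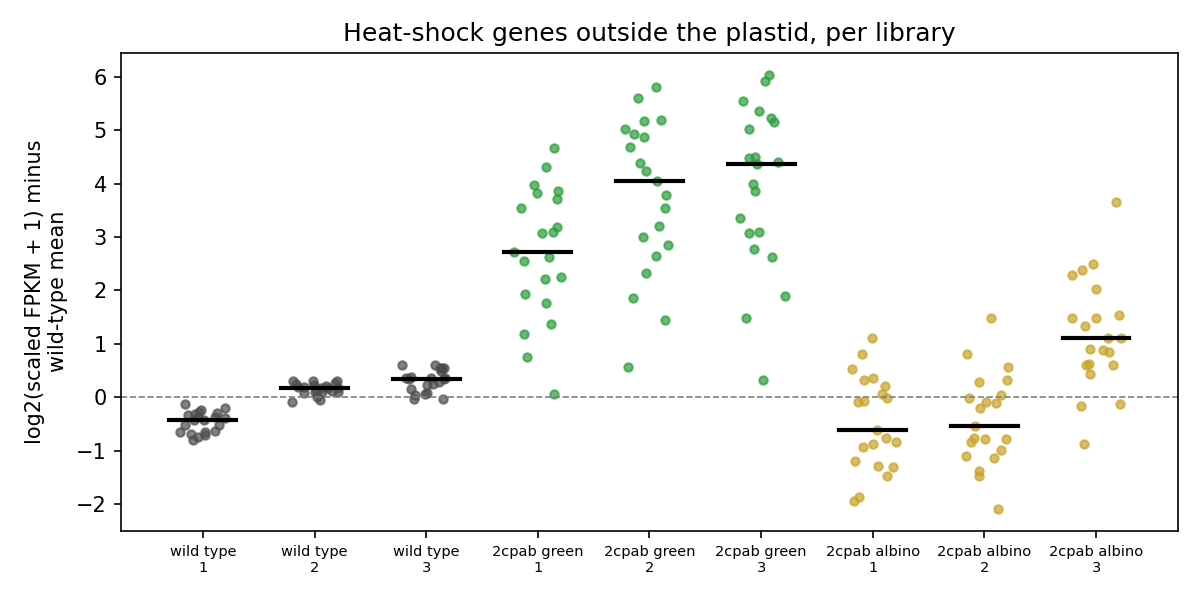
Log2(scaled FPKM + 1) of the 21 measured heat-shock genes outside the plastid in each library, minus each gene's wild-type mean (vertical axis); each library is a column of points with its median. The green medians are 2.72, 4.04 and 4.37, the wild-type medians -0.42 to 0.34, and the albino medians -0.62, -0.55 and 1.1.

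A pair of plastid chaperone genes and 6 of 12 genes of the mitochondrial stress response also rose in green seedlings. Among 19 plastid chaperone genes, 2 rose and 0 fell: HSP21, the small heat-shock protein of the chloroplast, from 0.209 ± 0.0939 to 28.7 ± 15.1 (4.45 ± 0.44, adjusted p = 0.000651), and CLPB3, a disaggregating chaperone, from 27.8 ± 2.23 to 99.9 ± 40.9 (1.71 ± 0.27, adjusted p = 0.00466). The median of that list was 0.05 and the set did not pass (camera adjusted p = 0.282), but without green replicate 1 it did (0.00387) and 4 members were higher. Of 12 genes of the mitochondrial dysfunction response, 6 rose and 0 fell (median 1.01; camera adjusted p = 8.94e-05, adjusted p = 0.270 with an estimated correlation). The largest were the mitochondrial small heat-shock protein HSP23.5, at 3.41 ± 0.35 (adjusted p = 0.000757), UPOX at 2.22 ± 0.22 (adjusted p = 0.000651) and AT12CYS-2 at 1.80 ± 0.24 (adjusted p = 0.00214). Adjusted over the list alone, both counts were the same.

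Genes of photosynthesis and pigment synthesis differed little between green mutants and the wild type. Light-harvesting genes had a median of -0.20 with 0 of 20 called; LHCB1.3 was at 7581 ± 1184 against 8789 ± 1758 (-0.21 ± 0.22, adjusted p = 0.663). Of 33 nuclear genes of the photosystems and electron transport, 4 fell, among them ferredoxin FD2 by 1.04 ± 0.21 (adjusted p = 0.0144) and photosystem I subunit PSAF by 0.95 ± 0.19 (adjusted p = 0.0159). Of 28 tetrapyrrole genes 3 fell: HEMA1 and HEMA2, which encode glutamyl-tRNA reductases at the start of the pathway, by 1.27 ± 0.22 (adjusted p = 0.00656) and 1.17 ± 0.11 (adjusted p = 0.000651), and the ferrochelatase FC1 by 1.05 ± 0.17 (adjusted p = 0.00512). None of 25 nuclear genes of plastid translation passed, with PSRP5 at -0.04. Adjusted over the list alone, these counts were the same. As sets these lists were lower than other genes (camera adjusted p = 0.0233 for light harvesting, 0.00386 for photosystems, 0.00246 for tetrapyrroles and 0.0473 for translation), each at adjusted p = 0.890 with an estimated correlation. The light-harvesting and photosystem sets were lost with quantile normalization (0.281 and 0.0894). All of them rested on single libraries: without green replicate 1 the adjusted p values were 0.454, 0.582, 0.120 and 0.929, with translation turned to higher, and without wild-type replicate 1 they were 0.625, 0.200, 0.235 and 0.375. Translation was lost also without wild-type replicate 2 (0.0700), albino replicate 2 (0.0520) or albino replicate 3 (0.0569). It was lost with a pseudocount of 0.1 (0.0532), the stricter filter (0.0527), median-of-ratios scaling (0.0538), only the 6 libraries compared (0.0559) or the replicate block (0.0543). The photosystem counts went to 2 without wild-type replicate 1 or green replicate 1. The photosynthesis lists together took 16.5% of summed FPKM in green replicate 1, 21.2% in replicate 2 and 19.4% in replicate 3. The means were 19.0 ± 2.33% over the green and 20.9 ± 2.26% over the wild-type libraries. Across tested genes, green replicate 1 correlated with the albino libraries at 0.931 to 0.937, against 0.898 to 0.911 for green replicates 2 and 3. Little difference in the group mean therefore need not hold for green replicate 1.

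The other plastid lists gave few calls in green seedlings, and none of their sets passed with all libraries. In the thiol-redox list 1 of 25 genes rose, the thioredoxin-like ACHT4 (0.84 ± 0.14, adjusted p = 0.00528). In carotenoid and isoprenoid synthesis 1 of 20 rose, the beta-carotene hydroxylase BCH1 (1.26 ± 0.19, adjusted p = 0.00335). Plastid proteases (0 of 17; FTSH2 -0.05), photorespiration (0 of 13; SHM1 0.06) and the plastid genome's photosynthesis genes (0 of 18; psbA 0.31) gave no call, although the set of plastid photosynthesis genes passed without wild-type replicate 2 (0.0252). Of 24 Calvin-Benson genes 1 fell, RPE (-0.65), lost without wild-type replicates 1 or 3, green replicates 1 or 2 or albino replicates 1, 2 or 3 (adjusted p from 0.0522 to 0.0916). None of them passed when adjusted over the list alone, and their median of 0.01 and mean of -0.01 differ in sign. Of 22 genes of plastid transcription 1 rose, the sigma factor SIG4 (1.03 ± 0.21, adjusted p = 0.0159, lost without green replicate 2, adjusted p = 0.0611); adjusted over the list alone 2 rose and 1 fell. Of 20 import genes 1 rose, TIC20-IV (0.48), lost without wild-type replicates 1 or 2 or green replicates 1 or 2 (adjusted p from 0.0557 to 0.0802). Of 5 plastid genes with nuclear-type promoters 1 rose, clpP1 (0.91), lost without green replicates 1 or 3 (adjusted p from 0.0526 to 0.0760). Of 13 regulators of light and retrograde signalling 2 rose, CGA1 and PIF1 (0.75 and 0.58), and 1 fell, EX1 (-0.38). CGA1 was lost without wild-type replicates 2 or 3 or green replicates 1 or 2 (adjusted p from 0.0641 to 0.0880). PIF1 was lost without wild-type replicates 2 or 3, green replicates 1, 2 or 3 or albino replicates 1 or 2 (adjusted p from 0.0640 to 0.152), and EX1 without wild-type replicate 1, green replicates 1, 2 or 3 or albino replicates 1, 2 or 3 (adjusted p from 0.0514 to 0.109). For lists without another count here, the results adjusted over the list alone were the same. The camera adjusted p values were 0.959 for thiol redox, 0.534 for carotenoids, 0.699 for proteases and for plastid photosynthesis genes alike, 0.645 for photorespiration, 0.901 for the Calvin-Benson cycle, 0.604 for transcription, 0.238 for import, 0.279 for nuclear-type promoters and 0.677 for the regulators, whose median of -0.02 and mean of 0.11 differ in sign. With green replicate 1 as the only green library, a setting chosen after the results were seen, 7 of these sets passed with medians below 0: the Calvin-Benson cycle (5.82e-05, median -0.38), photorespiration (0.00235, -0.34), thiol redox and proteases (0.00488 each, -0.22 and -0.19), carotenoids (0.0154, -0.14), import (0.0176, -0.20) and transcription (0.0455, -0.14).

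Some seed, abscisic acid and starch genes were higher in green mutants, and some genes of oxidative stress lower. Of 9 seed storage and oil-body genes 5 rose (7 adjusted over the list alone; median 1.64), with the cruciferin CRA1 at 25.6 ± 2.82 against 4.80 ± 3.04 (2.34 ± 0.39, adjusted p = 0.00587). Of 10 genes of abscisic acid and cold 3 rose (6 adjusted over the list alone), with COR15A, a cold-induced protein of the chloroplast stroma, at 1.18 ± 0.19 (adjusted p = 0.00512). Of 11 starch genes 4 rose (4 also adjusted over the list alone), led by the debranching enzyme ISA3 at 0.69 ± 0.12 (adjusted p = 0.00800). Of 14 genes that respond to reactive oxygen 3 fell, with the iron-storage gene FER1 down from 333 ± 56.9 to 109 ± 24.4 (-1.61 ± 0.16, adjusted p = 0.000722), and 1 rose, the peroxidase APX2, which was listed at 0 in wild-type replicates 1 and 2. Of 17 flavonoid genes 1 rose, GSTF12 (1.2), lost without wild-type replicates 2 or 3 or green replicates 1, 2 or 3 (adjusted p from 0.0552 to 0.0778). Against other genes the sets passed for seed storage (camera adjusted p = 2.10e-05), abscisic acid (0.000151), flavonoids (0.0125), starch (0.0314) and reactive oxygen (0.0473). With an estimated correlation these became adjusted p = 0.593 for seed storage and abscisic acid and adjusted p = 0.890 for the others. The starch set was lost without wild-type replicates 2 or 3 or green replicate 2 (adjusted p from 0.00389 to 0.106 over the 9 libraries left out in turn). The starch set was lost too without green replicates 2 and 3 (0.263). The reactive-oxygen set was lost without wild-type replicates 1, 2 or 3 or green replicate 1 (adjusted p from 0.00537 to 0.201 over the 9 libraries left out in turn), and with a pseudocount of 0.1 (0.0597), median-of-ratios scaling (0.0706) or quantile normalization (0.0712). With fry, only the heat-shock and mitochondrial dysfunction sets passed in green seedlings. Counts in these lists were as fragile: without wild-type replicate 3 they were 2 for seed storage, 1 for abscisic acid, 1 for starch and 1 for the fallen reactive-oxygen genes, and without green replicate 2 they were the same; without wild-type replicate 1 they were 3, 1, 2 and 1. Without green replicate 1 the last 3 were 1 each, and without albino replicate 1 or 2 abscisic acid fell to 1 and starch to 2, with abscisic acid at 1 and reactive oxygen at 5 without albino replicate 3.

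The remaining lists did not pass as sets in green seedlings with all libraries. Of 21 antioxidant enzymes 2 fell, the superoxide dismutase FSD1 from 564 ± 144 to 239.9 ± 24.8 (-1.2 ± 0.17, adjusted p = 0.00291) and the stromal peroxidase sAPX (-0.91 ± 0.12, adjusted p = 0.00178). Of 11 carbon-starvation genes 1 rose, KMD4 (2.09 ± 0.22, adjusted p = 0.000764), while the list median was -0.39; that set passed as lower with organelle genes removed (0.0458), with the scaling undone (0.0469), without wild-type replicate 3 (0.0392) or green replicate 1 (0.00387, with 4 members lower). Of 10 jasmonate genes VSP2 rose (0.93 ± 0.18, adjusted p = 0.0114) and 3 fell, among them the repressor JAZ5 (-1.27 ± 0.25, adjusted p = 0.0127). None were lower without wild-type replicate 3 (JAZ5 adjusted p = 0.0517), 5 without green replicate 3. Adjusted over the list alone, 4 rose and 5 fell. Of 5 salicylate genes PAD4 fell (-0.65 ± 0.12, adjusted p = 0.0109), and PR2 passed as higher, listed at 0 in all wild-type libraries and at 2.60, 1.01 and 2.87 in the green ones. Of 8 genes that mobilise seed reserves 1 rose, the isocitrate lyase gene ICL (1.67 ± 0.35, adjusted p = 0.0175, lost without wild-type replicate 1, adjusted p = 0.0549). Root markers (0 of 11; CASP1 -0.45), stomatal markers (0 of 4; MYB60 -0.08) and cell-division genes (0 of 7; KNOLLE 0.19) gave no call, except that the root set passed as lower without wild-type replicate 1 (0.0232), where CASP1 passed too (0.0207). For these lists other than jasmonate, counts adjusted over the list alone were the same. Camera gave adjusted p values of 0.340 for antioxidant enzymes, 0.0702 for carbon starvation, 0.507 for jasmonate, 0.809 for salicylate (tested as lower, with a median of 0.05), 0.534 for reserve mobilisation, 0.253 for root markers and 0.224 for stomatal markers and for cell division alike. With green replicate 1 as the only green library, 3 of these sets passed: jasmonate (0.0128, median -0.75), reserve mobilisation (0.00488, 0.25) and cell division (0.0154, 0.21).

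Over all genes, 1751 of 19731 passed between green mutants and the wild type, 733 higher and 1018 lower, and 491 of them changed at least 2-fold (266 higher, 225 lower). The largest falls after 2CPA and 2CPB were in AT3G05945, a long noncoding RNA gene (chromosome 3 from 11510090 to 11510510; -2.49 ± 0.43, adjusted p = 0.00688), and in CYP94C1, which oxidises jasmonoyl-isoleucine (-2.20 ± 0.34, adjusted p = 0.00410). They were followed by AT3G44870 (-2.10 ± 0.43, adjusted p = 0.0158, lost without wild-type replicate 3, adjusted p = 0.0591), AT5G38700 (-2.05 ± 0.17, adjusted p = 0.000335), PP2-A5 (-1.99 ± 0.18, adjusted p = 0.000462) and the calmodulin-like CML38 (-1.94 ± 0.30, adjusted p = 0.00391). AT3G05945 followed the targeted genes between libraries, at 4.59%, 27.5% and 23.2% of its wild-type mean in green replicates 1, 2 and 3. The groups did not overlap for 23.8% of genes, where chance gives 10%. In simulated data the 50 genes changed at each fold were not weakly expressed, and noise was independent. Of these genes, 82% at 0.5-fold and 78% at 2-fold were recovered, with 5 false calls. The number of genes fell to 1038 without wild-type replicate 3 and to 1126 without green replicate 2, was 1373 without green replicate 1, and was 1071 with only the 6 libraries compared and 729 with green replicate 1 as the only green library.

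Albino seedlings held much less RNA of nuclear photosynthesis genes than the wild type. All 20 light-harvesting genes fell (median -3.42), as did all 33 genes of the photosystems and electron transport (median -2.92) and all 13 of photorespiration (median -2.31). Of 24 Calvin-Benson genes 21 fell and 1 rose. LHCB2.3, an antenna protein of photosystem II, went from 502 ± 237 to 8.33 ± 1.51 (-5.67 ± 0.27, adjusted p = 1.77e-06). PSAH2 of photosystem I went from 1571 ± 307 to 138 ± 11 (-3.48 ± 0.18, adjusted p = 2.03e-06), and the small Rubisco subunit RBCS2B from 4527 ± 853 to 139 ± 31.7 (-5.03 ± 0.29, adjusted p = 2.90e-06). LHCB1.4 fell by 5.07 ± 0.23 (adjusted p = 1.38e-06) and the glycolate transporter PLGG1 by 3.11 ± 0.18 (adjusted p = 2.52e-06). Single members of the LHCB and RBCS families share sequence with near-identical copies, so their own levels are uncertain. Together the photosynthesis lists took 3.25 ± 0.252% of summed FPKM in albino seedlings against 20.9 ± 2.26% in the wild type and 19.0 ± 2.33% in green mutants (exact two-sided permutation p = 0.1 for albino against either group and 0.5 for green against the wild type; 3 against 3 cannot give less than 0.1). The sets passed with camera adjusted p values of 1.79e-19, 1.75e-27, 2.71e-12 and 7.82e-14 in this order, each at adjusted p = 0.255 with an estimated correlation. Counts adjusted over the list alone were the same, except that 2 Calvin-Benson genes rose; 3 rose without wild-type replicate 2.

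Pigment synthesis and chloroplast redox, protease and ribosomal genes fell with them in albino seedlings. All 28 tetrapyrrole genes fell (median -1.34), among them GUN4, which activates magnesium chelatase (-2.74 ± 0.25, adjusted p = 2.44e-05), the cyclase CRD1 (-2.71 ± 0.18, adjusted p = 4.74e-06) and the chelatase subunit CHLH (-2.56 ± 0.20, adjusted p = 1.05e-05). All 20 carotenoid and isoprenoid genes fell (median -0.96), with phytoene synthase PSY at -2.14 ± 0.18 (adjusted p = 1.49e-05). In the thiol-redox list 20 of 25 genes fell and 2 rose (median -1.1), with thioredoxin TRXF1 at -2.63 ± 0.17 (adjusted p = 4.49e-06) and peroxiredoxin PRXQ at -2.28 ± 0.15 (adjusted p = 5.73e-06). All 17 plastid proteases fell (median -0.81), with FTSH5 of the thylakoid protease at -1.45 ± 0.12 (adjusted p = 1.82e-05), and 24 of 25 nuclear genes of plastid translation fell (median -1.56), with PRPL11 at -1.89 ± 0.15 (adjusted p = 9.94e-06). Among 19 plastid chaperones 10 fell and 2 rose (median -0.64), with CPN60B1 of the stromal chaperonin at -0.93 ± 0.15 (adjusted p = 0.000767). Counts adjusted over the list alone were the same, except that 12 chaperones fell and 1 translation gene rose. With camera the adjusted p values were 9.46e-18 for tetrapyrroles, 8.50e-11 for carotenoids, 1.38e-09 for thiol redox, 8.44e-10 for proteases and 3.88e-16 for translation, each at adjusted p = 0.255 with an estimated correlation, and 0.00108 for chaperones (adjusted p = 0.384 with an estimated correlation). Under TPM fewer members passed as lower, 10 proteases, 13 carotenoid genes and 7 chaperones, with 4 chaperones higher.

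Genes that transcribe, supply and regulate the plastid were divided in albino seedlings, and their direction as families depended on the scaling. Of 20 import genes 12 fell and 1 rose: TIC62 fell by 2.69 ± 0.12 (adjusted p = 1.38e-06) and TIC20-IV rose by 1.5 ± 0.11 (adjusted p = 7.90e-06). The median was -0.40 but turned to 0.07 under TPM, with 7 higher and 5 lower (camera adjusted p = 0.00158, adjusted p = 0.385 with an estimated correlation). Of 22 genes of plastid transcription 8 fell, among them the sigma factors SIG1 (-1.43 ± 0.20, adjusted p = 0.000372) and SIG2 (-1.27 ± 0.14, adjusted p = 7.80e-05), and 2 rose, and the median of -0.07 turned to 0.40 under TPM, with 12 higher and 5 lower (camera adjusted p = 0.112). Of 13 regulators of light and retrograde signalling 7 fell and 3 rose (8 and 4 adjusted over the list alone), with GLK1 and GLK2, activators of photosynthesis genes, at -1.76 ± 0.21 (adjusted p = 0.000127) and -1.22 ± 0.21 (adjusted p = 0.00122). Their median of -0.29 turned to 0.15 under TPM (camera adjusted p = 0.0852; 0.00665 with fry and 0.0454 without wild-type replicate 3, where, as without albino replicate 1 or 2, 1 rose). Of 18 photosynthesis genes on the plastid genome 4 rose and 3 fell (median 0.15, camera adjusted p = 0.767), with psbA, the D1 protein of photosystem II, at 64.4 ± 4.70 against 18.4 ± 8.47 (1.84 ± 0.31, adjusted p = 0.000992) and psbE at 1.46 ± 0.29 (adjusted p = 0.00299). Only 1 fell without wild-type replicate 3 or any single albino library. Of 5 plastid genes with nuclear-type promoters 4 rose and 1 fell (camera adjusted p = 0.154; 0.0108 without a filter and 0.0253 with fry), with clpP1 at 2.26 ± 0.21 (adjusted p = 2.41e-05) and rpoB, a subunit of the plastid RNA polymerase, at -1.28 ± 0.19 (adjusted p = 0.000489). Only 2 rose without wild-type replicate 2 or albino replicate 1 or 2. Poly(A) selection captures plastid transcripts poorly, and overlapping plastid genes are uncertain. Counts not given otherwise were the same adjusted over the list alone.

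Most reserve-mobilisation, flavonoid and abscisic acid genes rose in albino seedlings. Of 8 genes that mobilise seed reserves 7 rose (median 1.22), with ICL and MLS, the enzymes particular to the glyoxylate cycle, up from 12.2 ± 2.08 to 229.5 ± 11.9 (4.14 ± 0.35, adjusted p = 1.70e-05) and from 7.39 ± 2.01 to 49.8 ± 7.79 (2.61 ± 0.36, adjusted p = 0.000288). Of 9 seed storage and oil-body genes 4 rose, among them oleosin OLEO2 (2.08 ± 0.28, adjusted p = 0.000294). Of 17 flavonoid genes 15 rose (median 1.25), with dihydroflavonol reductase DFR at 2.44 ± 0.42 (adjusted p = 0.00124). Of 10 genes of abscisic acid and cold 8 rose, with RAB18 at 2.69 ± 0.40 (adjusted p = 0.000476) and COR15A at 2.19 ± 0.19 (adjusted p = 1.95e-05). Of 12 mitochondrial dysfunction genes 8 rose and 2 fell, with the glucosyltransferase UGT74E2 at 3.66 ± 0.38 (adjusted p = 4.97e-05) and UPOX at 2.96 ± 0.22 (adjusted p = 7.90e-06). Of 11 carbon-starvation genes 6 rose and 1 fell, with KMD4 at 3.56 ± 0.22 (adjusted p = 3.63e-06). In camera tests adjusted p values were 0.00111 for reserve mobilisation (adjusted p = 0.282 with an estimated correlation), 0.0152 for seed storage (adjusted p = 0.460 with an estimated correlation), 5.49e-06 for flavonoids, 0.000861 for abscisic acid and 0.00791 for mitochondrial dysfunction (each at adjusted p = 0.255 with an estimated correlation), and 0.0265 for carbon starvation (adjusted p = 0.436 with an estimated correlation). Counts adjusted over the list alone were the same. Under TPM the sets of seed storage (0.241), mitochondrial dysfunction (0.211) and carbon starvation (0.236) no longer passed, nor with organelle genes removed (0.240, 0.195 and 0.197) or the scaling undone (0.240, 0.185 and 0.207), and carbon starvation was also lost without albino replicate 3 (0.0649).

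Most genes that respond to reactive oxygen fell in albino seedlings, while defence, antioxidant and jasmonate genes went both ways. Of the 14 reactive-oxygen genes 10 fell and 2 rose (median -2.04), with the transcription factors WRKY40, from 375 ± 25.2 to 16.4 ± 8.09 (-4.53 ± 0.30, adjusted p = 4.86e-06), and RRTF1 (-5.23 ± 0.59, adjusted p = 8.68e-05) among them. Of 21 antioxidant enzymes 8 rose and 7 fell: the copper/zinc superoxide dismutase CSD1 rose from 96.6 ± 38.0 to 481 ± 50.1 (2.37 ± 0.23, adjusted p = 3.78e-05). The iron enzyme FSD1 fell by 2.54 ± 0.17 (adjusted p = 5.58e-06) and the thylakoid peroxidase tAPX by 2.18 ± 0.11 (adjusted p = 2.03e-06). Of 5 salicylate genes 4 rose and 1 fell, with ICS1, the main enzyme of salicylate synthesis, at 1.22 ± 0.14 (adjusted p = 8.30e-05), and PR2 at 8.29, 12.7 and 21.5 where the wild type was listed at 0. Of 10 jasmonate genes 5 rose and 5 fell, with VSP2 at 2.79 ± 0.18 (adjusted p = 4.43e-06) and the repressor JAZ1 at -1.99 ± 0.24 (adjusted p = 0.000120); 3 rose without albino replicate 1 or 2. Of 21 heat-shock genes outside the plastid 2 rose and 2 fell (1 and 0 adjusted over the list alone), with HSP15.7 at 2.08 ± 0.58 (adjusted p = 0.0154), lost without wild-type replicate 1 (adjusted p = 0.0502). Albino replicate 3 stood apart here, with a list median of 1.1 over the wild-type mean against -0.62 and -0.55 in the other albino libraries; without it 2 rose and 4 fell. Of 11 starch genes 6 fell and 2 rose (6 and 3 adjusted over the list alone), with the adenosine diphosphate glucose synthase subunit APL1 at -2.01 ± 0.14 (adjusted p = 6.08e-06). The camera adjusted p values were 0.000168 for reactive oxygen (adjusted p = 0.284 with an estimated correlation) and 0.0299 for salicylate (adjusted p = 0.384 with an estimated correlation; lost under TPM at 0.167, with organelle genes removed at 0.147, with the scaling undone at 0.156, with the stricter filter at 0.0697, without wild-type replicate 2 at 0.0541 and without albino replicate 3 at 0.0580). They were 0.952 for antioxidant enzymes (median 0.20, mean -0.08), 0.871 for jasmonate, 0.998 for heat shock (median -0.11, mean 0.09) and 0.0725 for starch (0.0323 without wild-type replicate 3, 0.0101 under TPM, 0.00948 with organelle genes removed, 0.0118 with the scaling undone, 0.0478 without a filter and 0.00358 with fry). Under TPM the medians of jasmonate and heat shock turned to 0.29 and 0.36, with 6 heat-shock genes higher. Counts not given otherwise were the same adjusted over the list alone.

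Markers of other tissues moved less than the photosynthesis genes in albino seedlings. Of 4 stomatal markers 3 fell, KAT1 (-1.18 ± 0.13, adjusted p = 8.41e-05), FAMA (-0.84 ± 0.10, adjusted p = 0.000102) and MYB60 (-0.72 ± 0.10, adjusted p = 0.000300). Of 11 root markers 5 rose, with CASP5 of the endodermis at 1.55 ± 0.25 (adjusted p = 0.000905); 3 rose without albino replicate 2 or 3. Of 7 cell-division genes the cyclin CYCB1;1 rose (0.55 ± 0.10, adjusted p = 0.00142) and CYCB1;2 fell (-0.35 ± 0.09, adjusted p = 0.0106), but CYCB1;2 turned to 0.09 under TPM and the list median turned from 0.00 (mean 0.03) to 0.45, with 4 higher. Camera gave adjusted p values of 0.0187 for stomatal (adjusted p = 0.255 with an estimated correlation), 0.132 for root (0.0398 without wild-type replicate 2) and 0.871 for cell-division genes. Counts adjusted over the list alone were the same.

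Over all genes, 8581 of 19731 passed between albino seedlings and the wild type, 4613 higher and 3968 lower, and 2439 changed at least 2-fold (912 higher, 1527 lower). AIG1, a defence gene listed at 0 in 2 wild-type libraries, stood at 36.2 ± 9.94 in albino seedlings and rose most. It was followed by PDF1.4 (4.75 ± 0.24, adjusted p = 2.03e-06) and the nuclease ENDO2 (4.63 ± 0.25, adjusted p = 2.22e-06). The caleosin RD20, also listed at 0 in a wild-type library, reached 29.5 ± 8.55, and the calmodulin-like CML41 rose by 4.22 ± 0.27 (adjusted p = 4.53e-06). After 2CPB, LHCB2.3, RRTF1 and 2CPA, the largest fall was in the transcription factor DDF1 (-5.15 ± 0.47, adjusted p = 2.40e-05). The groups did not overlap for 56.0% of genes, where chance gives 10%. In simulated data, again without weakly expressed changed genes, 70% of genes at 0.5-fold and 84% of those at 2-fold were recovered, with 9 false calls. The split into higher and lower genes depends on the scaling. The deposited values set equal 75th percentiles, under which the median of all genes lay at 0.07. Under TPM it lay at 0.51, 14316 genes passed and 85.3% of them were higher, against 53.8% here. With the organelle genes removed or the scaling undone (the latter chosen after seeing the data) 85.5% and 83.7% were higher. Median-of-ratios scaling and quantile normalization stayed near the deposited split. They gave 46.3% and 55.8% higher, with medians of all genes at 0.02 and 0.06. The changes given here are relative to the deposited scaling.

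The comparison of albino with green seedlings repeated the loss of photosynthesis RNA and added the heat-shock genes. All 20 light-harvesting, 33 photosystem and 13 photorespiration genes were lower in albino seedlings (medians -3.16, -2.70 and -2.33), as were 21 of 24 Calvin-Benson genes, with 1 higher. LHCB2.3 fell by 5.50 ± 0.27 (adjusted p = 2.90e-06), PSBS, which switches the antenna to heat dissipation, by 3.30 ± 0.20 (adjusted p = 5.38e-06), and the carbonic anhydrase CA1 from 1286 ± 299.5 to 43.3 ± 9.76 (-4.86 ± 0.22, adjusted p = 2.37e-06). Of 21 heat-shock genes 19 were lower in albino than in green seedlings and 0 higher (21 lower adjusted over the list alone; median -3.65), with the disaggregase HSP101 at 11.9 ± 10.4 against 333 ± 144 (-4.87 ± 0.51, adjusted p = 8.45e-05) and HSP17.6C at -5.42 ± 0.73 (adjusted p = 0.000381). With green replicate 1 as the only green library 12 were lower. Of 19 plastid chaperones 14 were lower, with HSP21 (-3.99 ± 0.44, adjusted p = 0.000115) and CLPB3 (-2.24 ± 0.27, adjusted p = 0.000209) first, and 6 with that single green library. The iron-regulated genes BHLH100, a transcription factor of the iron-deficiency response, and CYP82C4 were also among the 8 largest falls (-5.45 ± 0.30, adjusted p = 4.08e-06 and -4.95 ± 0.22, adjusted p = 2.37e-06). Further lower were 26 of 28 tetrapyrrole (27 adjusted over the list alone), 19 of 20 carotenoid (20), 19 of 25 thiol-redox (21, with 1 higher), 16 of 17 protease (17) and 24 of 25 translation genes. For these lists the camera adjusted p was 9.20e-30 for photosystems, 2.25e-21 for light harvesting, 6.46e-16 for the Calvin-Benson cycle, 1.16e-13 for photorespiration, 5.20e-17 for translation and for tetrapyrroles alike. It was 8.66e-12 for heat shock, 1.36e-11 for carotenoids, 3.28e-11 for thiol redox, 1.07e-10 for proteases and 2.23e-05 for chaperones, each of the lists so far at adjusted p = 0.254 with an estimated correlation.

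**Figure D3:**
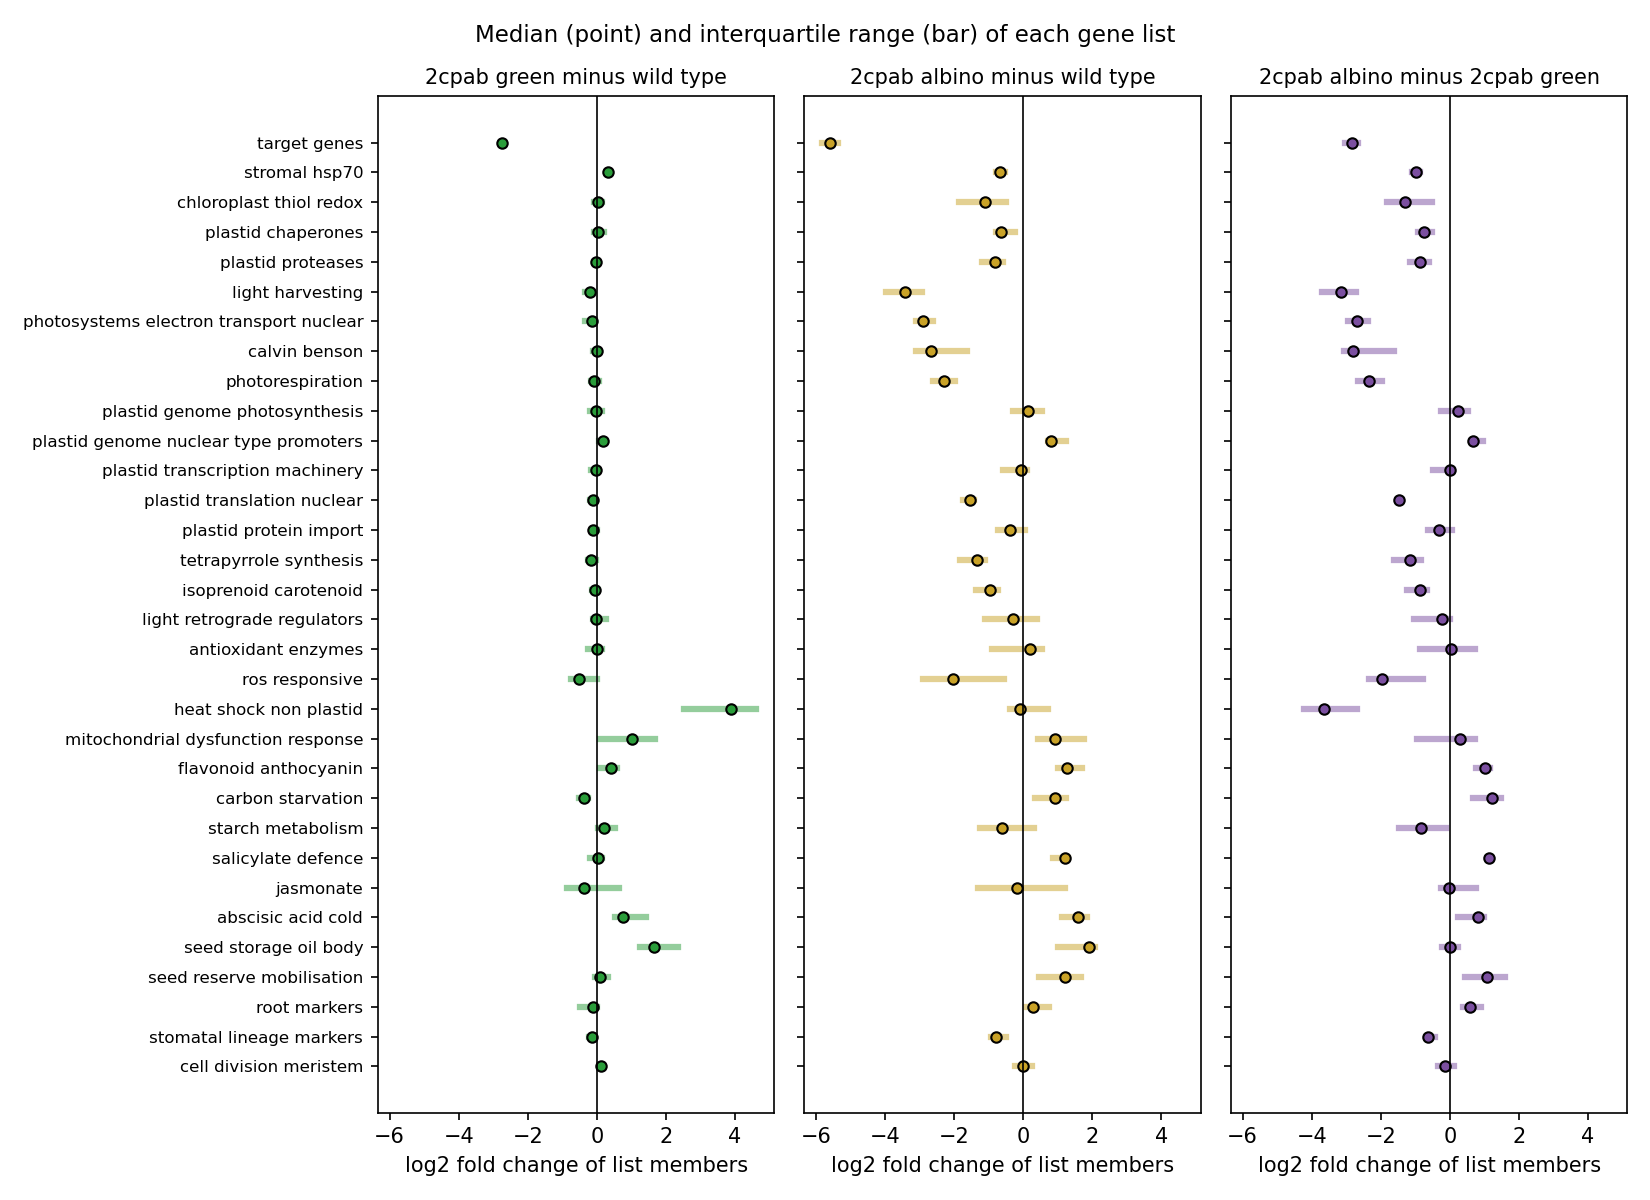
Log2 fold change (horizontal axes) of the members of each of the 32 gene lists in the 3 comparisons (panels); the point is the list's median and the bar its interquartile range. Light-harvesting genes sit at -0.20 in green and -3.42 in albino seedlings against the wild type, and heat-shock genes at 3.88 and -0.11; under TPM the last turned to 0.36.

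Other lists also differed between albino and green seedlings. Of 8 reserve-mobilisation genes 7 were higher in albino seedlings (ICL 2.47 ± 0.35, adjusted p = 0.000506), as were 13 of 17 flavonoid genes (14 adjusted over the list alone; GSTF12 1.25 ± 0.27, adjusted p = 0.00538) and 4 of 5 salicylate genes (ICS1 1.17 ± 0.14, adjusted p = 0.000152). Also higher were 8 of 11 carbon-starvation genes with 1 lower (10 and 1; BCAT2 2.40 ± 0.29, adjusted p = 0.000211) and 7 of 11 root markers (9; CASP5 1.38 ± 0.25, adjusted p = 0.00223). Of 10 genes of abscisic acid and cold 6 were higher and 1 lower (RD29A 1.48 ± 0.16, adjusted p = 0.000105). Lower were 7 of 11 starch genes (APL1 -1.93 ± 0.14, adjusted p = 1.2e-05), 11 of 14 reactive-oxygen genes with 2 higher (WRKY40 -3.21 ± 0.30, adjusted p = 4.42e-05) and 3 of 4 stomatal markers (KAT1 -0.86 ± 0.13, adjusted p = 0.000791). Lower too were 6 of 13 light and retrograde regulators with 1 higher (GLK1 -1.73 ± 0.21, adjusted p = 0.000201) and 10 of 20 import genes with 2 higher (11 and 2; TIC62 -2.44 ± 0.12, adjusted p = 2.90e-06). With camera the adjusted p values were 0.000231 for reserve mobilisation, 4.25e-05 for flavonoids, 0.00250 for salicylate, 0.000663 for carbon starvation, 0.000666 for starch, 0.000136 for reactive oxygen and 0.0284 for stomatal markers, each at adjusted p = 0.254 with an estimated correlation. They were 0.01 for root markers (adjusted p = 0.272 with an estimated correlation), 0.0186 for the regulators (adjusted p = 0.339 with an estimated correlation), 0.00647 for import and 0.0422 for abscisic acid (adjusted p = 0.390 with an estimated correlation for both). The abscisic acid set was lost under TPM (0.450), with organelle genes removed (0.391), the scaling undone (0.379), a pseudocount of 0.1 (0.0537), the stricter filter (0.0816) or quantile normalization (0.0564), and without wild-type replicate 3 or green replicates 1 or 3 (adjusted p from 0.0103 to 0.101 over the 9 libraries left out in turn). The root set was lost under TPM (0.0629), with organelle genes removed (0.0550) and with the scaling undone (0.0540). The stomatal set was lost without albino replicate 3 (0.0521). Without green replicate 3, or without albino replicate 1 or 2, 3 abscisic acid genes and 4 root markers were higher, and without albino replicate 3 also 4 root markers. With green replicate 1 as the only green library, 3 flavonoid, 4 carbon-starvation and 0 root genes were higher. Under TPM the medians of import and of the regulators turned from -0.30 and -0.22 to 0.15 and 0.17.

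Sets that did not pass between the mutant groups included plastid transcription (2 of 22 higher and 6 lower, camera adjusted p = 0.205; median 0.00, mean -0.24; SIG4 -1.98 ± 0.21, adjusted p = 9.46e-05). Plastid photosynthesis genes did not pass (4 of 18 higher, 0.478; psbE 1.74 ± 0.29, adjusted p = 0.00140), nor did plastid genes with nuclear-type promoters (3 of 5 higher and 1 lower, 4 and 1 adjusted over the list alone, 0.234; 0.0254 without a filter). Antioxidant enzymes were divided, 10 of 21 higher and 7 lower (0.730; CSD2 1.79 ± 0.16, adjusted p = 3.27e-05), as were mitochondrial dysfunction genes, 5 of 12 higher and 4 lower (6 and 4 adjusted over the list alone, 0.681; HSP23.5 -2.69 ± 0.35, adjusted p = 0.000305). Their median was 0.29 and their mean -0.01, with 3 higher without green replicate 3 or albino replicate 1. Jasmonate genes gave 4 of 10 higher and 2 lower (0.659, 0.0494 without green replicates 2 and 3; VSP2 1.85 ± 0.18, adjusted p = 5.41e-05) and seed storage genes 1 of 9 lower, SESA2 (0.878; -2.36 ± 0.52, adjusted p = 0.00643). Cell-division genes gave 1 of 7 higher and 2 lower (1 and 3 adjusted over the list alone, 0.358; KNOLLE -0.45 ± 0.09, adjusted p = 0.00490). Median and mean differ in sign for jasmonate (-0.01 and 0.19) and seed storage (0.01 and -0.18). Under TPM the median of jasmonate genes turned from -0.01 to 0.42 and that of cell division from -0.13 to 0.30, and KNOLLE no longer passed (0.909).

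Over all genes, 7131 of 19731 passed between albino and green seedlings, 3648 higher and 3483 lower in albino ones, and 1947 differed at least 2-fold (638 higher, 1309 lower). The largest rises were in the ribonuclease RNS1 (3.62 ± 0.26, adjusted p = 1.08e-05), RD20 (3.58 ± 0.27, adjusted p = 1.49e-05), AIG1 (3.40 ± 0.32, adjusted p = 5.02e-05) and AT4G35720 (3.34 ± 0.24, adjusted p = 1.13e-05). The groups did not overlap for 53.3% of genes, where chance gives 10%. Under TPM the median of all genes moved from 0.05 to 0.47, 13698 genes passed and 86.6% of them were higher, against 51.2% here. With the organelle genes removed or the scaling undone 86.7% and 84.7% were higher. Median-of-ratios scaling gave 45.1% and quantile normalization 55.6%. With green replicate 1 as the only green library 2655 genes passed.

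Many genes called in green mutants were also called in albino ones in the same direction, 407 higher and 768 lower in both, where independent lists would share 171 and 205. HEMA1, FER1 and FSD1 were lower in both groups, and UPOX, KMD4 and COR15A higher in both. Opposite calls were fewer than for independent lists, with 67 genes higher in green and lower in albino against 147, and 32 lower in green and higher in albino against 238. Across all 19731 genes, which are not independent replicates, the log2 fold changes correlated at r = 0.44, against 0.50 in simulations of unchanged groups that share simulated controls, and 67.2% had the same sign against 66.6%. Their covariance was 0.135 against a simulated 0.0147. Part of any excess may come from the shared wild-type libraries. Of the 1751 genes called in green mutants, 1175 were called in the same direction in albino ones (703 without wild-type replicate 3, 765 when each comparison used only its own 6 libraries, 604 with green replicate 1 as the only green library), and 1013 differed between both mutant groups.

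Plastid-encoded genes took a small part of the summed FPKM in every library, 0.411 ± 0.187% in the wild type, 0.713 ± 0.168% in green and 0.874 ± 0.0623% in albino seedlings (n = 3 each). The share was larger in albino seedlings than in the wild type by 0.463 and than in green ones by 0.162 percentage points, and in green seedlings than in the wild type by 0.302 (exact two-sided permutation p = 0.1, 0.1 and 0.2; the smallest possible is 0.1, so none can pass). Ribosomal RNA made up 78.8% to 92.8% of it. Without ribosomal RNA the differences were 0.0665, 0.0676 and -0.00110 percentage points in the same order. The difference between the mutant groups fell to 0.0648 without green replicate 3, and wild-type replicate 1 had the largest share of its group, 0.624%.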

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

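The tests of scaling, handling, mixing, mislabelling and shoot tissue were chosen only after the results were seen, while the tests of regrouped libraries were set before the data were examined.

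Heat-shock genes were higher in green seedlings but not as a set in albino ones, where 2 of 21 rose and 2 fell. This difference passed between the mutant groups (camera adjusted p = 8.66e-12, adjusted p = 0.254 with an estimated correlation). The authors' scaling does not explain the rise in green seedlings, since the lowest median of green minus wild type over 5 other scalings was 3.72. That test did not cover the difference between the mutant groups. Warmth or handling of the green seedlings at harvest could raise the same genes, and all 3 of 3 green libraries had list medians above every wild-type library, so this test cannot separate handling from genotype. Albino replicate 3 also had a list median above every wild-type library (1.1 against at most 0.34). Albino replicates 1 and 2 did not (-0.62 and -0.55). An effect of the mutation that is seen mainly in green seedlings and an effect of the harvest both stay open. Wild-type, green and albino plants harvested in mixed order, with HSP22 and HSP17.6C measured by quantitative PCR, would separate them.

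2CPA and 2CPB were higher in green replicates 2 and 3 than in green replicate 1. RNA with wild-type alleles of both genes mixed into replicates 2 and 3 could not be tested with genes that are low in green seedlings. Of 4813 genes, 3 were under 20% of the lowest wild-type library in green replicate 1 (2CPB, 2CPA and AT3G05945). There were 1 in replicate 2, 1 in replicate 3 and 0 in both replicates 2 and 3, too few to decide. Such a mix would also dilute genes that rose in green seedlings. The heat-shock list median over the wild-type mean was larger in replicates 2 and 3 (4.04 and 4.37) than in replicate 1 (2.72). Levels before any mixing are unknown, so these medians do not decide either. AT5G38700 kept 17.9% of its wild-type mean in replicate 2, less than 2CPA at 30.3% and 2CPB at 24.3%, but a single gene in 1 library excludes nothing. AT3G05945 kept 4.59% in replicate 1 and 27.5% and 23.2% in replicates 2 and 3. These lie near the shares of 2CPA (30.3% and 29.1%) and 2CPB (24.3% and 27.1%). A mix would give such shares, but 3 genes picked for being low in replicate 1 cannot decide. A mislabelled albino library does not explain green replicate 1, as 16.5% of its summed FPKM lay on photosynthesis genes. Reads across the insertion sites or genotyping of the seed stock would decide.

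Photosynthesis genes were lower in albino seedlings. The authors' scaling does not explain this, since the highest median of light-harvesting genes over 5 other scalings was -2.72. Less shoot tissue could lower all shoot genes, but the 4 stomatal markers kept a median of 51.9% of the wild-type level where light-harvesting genes kept 9.25%. The ranges were wide, 31.3% to 116% for the stomatal markers and 1.66% to 46.6% for light harvesting. Of 11 root markers 5 were higher and 0 lower in albino seedlings than in the wild type, so a partial loss of shoot tissue stays open. Tissue dissected before extraction would test what remains.

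Other results in which the mutant groups differed with opposite signs against the wild type were starch genes (camera adjusted p = 0.000666, adjusted p = 0.254 with an estimated correlation, medians 0.21 in green and -0.62 in albino seedlings), cpHSC70-1 (adjusted p = 0.00528) and cpHSC70-2 (adjusted p = 0.000952). Neither of the HSP70 genes passed in green seedlings against the wild type (adjusted p = 0.229 and 0.459), nor did cpHSC70-1 in albino ones (0.0759). The sign of cpHSC70-1 turned in albino seedlings under TPM (0.08), and those of both genes in green ones without green replicates 2 and 3 (-0.03 and -0.20). The starch set did not pass in albino seedlings against the wild type (camera adjusted p = 0.0725).

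Regrouped libraries gave as many called genes as the real groups in 1 of 10 splits for each comparison, the real split itself. The real counts were 1751, 8581 and 7131, and the highest other counts 2, 4 and 2. For gene lists between green mutants and the wild type it was 5 of 10 splits, with 12 real and 19 as the highest other. For albino against the wild type and against green it was 1 of 10, with 21 and 23 real and 19 and 22 as the highest others. With 10 splits the share cannot go under 0.1, and so not under 0.05. The number of lists that pass at the preset correlation thus hardly separates the real groups from other splits. Each other split still mixes libraries of both groups unevenly, so part of a real difference can remain in it.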

How the results depend on the processing

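The tests with the scaling undone, without genes listed at 0, and without green replicates 2 and 3 were chosen only after the results were seen.

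Where a value moved, the cause was not tested. Called genes numbered 1751 between green mutants and the wild type, 8581 between albino mutants and the wild type and 7131 between albino and green. They were 14316 and 13698 in the albino comparisons under TPM, 14388 and 13782 with organelle genes removed, and 13918 and 13070 with the scaling undone. In green against the wild type they were 1071 with only the 6 libraries compared. A required 2-fold change left 491, 2439 and 1947. Without green replicates 2 and 3, where the lone green library is assumed to vary like the other groups, they were 729 in green against the wild type and 2655 in albino against green. Leaving out single libraries gave 1038 (without wild-type replicate 3) to 1627 in green against the wild type, 6580 to 8752 in albino against the wild type and 5202 to 7472 in albino against green. Passing lists numbered 12, 21 and 23; with an estimated correlation all 3 counts were 0, with fry the green count was 2, and without green replicates 2 and 3 it was 21. CYCB1;2 in albino seedlings turned from a fall to 0.0896 under TPM, 0.0935 with organelle genes removed and 0.0383 with the scaling undone, none of them called. Plastid translation in green seedlings ran from an adjusted p of 0.000136 to 0.929 over the libraries left out in turn, and was reversed without green replicate 1 (0.929). Genes called in the same direction in both mutant groups, 1175, were 765 with the 6 libraries compared, 604 without green replicates 2 and 3, and 703 to 1169 with a library left out. The plastid share without ribosomal RNA differed by -0.00110 in green and 0.0665 in albino seedlings against the wild type. Of called named-gene results, 23 of 58, 85 of 100 and 75 of 103 passed in every setting that tested the gene. Some settings, such as the stricter filter, left some of these genes out.

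With the replicate number as a replicate block, 1784, 8621 and 7112 genes were called, of which 1547, 8240 and 6729 were among the main calls. The set of stromal HSP70 genes was then lost between albino and green (0.0513) and that of plastid translation in green against the wild type (0.0543), and carbon starvation passed in green (0.0374). Of named genes RPE (0.0577), RAB18 (0.0533) and CRU3 (0.0571) were lost in green against the wild type. Whether a shared replicate number marks a shared batch is unknown. Correlations between groups for the same number ran from -0.147 to 0.281, and in 5 of 9 such pairs the best match was the same number. The largest were 0.281 and 0.267, for numbers 2 and 3 between the wild type and green, so a shared batch of these groups stays open.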

Other observations

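The iron, copper and touch tests were chosen only after the results were seen; their predictions for unseen genes were written before those genes were looked at.

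Many genes of the iron-deficiency response were higher in green mutants and lower in albino ones. Of 11 chosen after their values were seen, 7 rose and 0 fell in green and 0 rose and 10 fell in albino seedlings. Adjusted over the list alone, 10 rose in green and 10 fell in albino seedlings. The transcription factor bHLH38 rose from 14.6 ± 4.37 to 107 ± 1.95 in green seedlings (2.83 ± 0.21, adjusted p = 0.000190) and fell to 5.01 ± 1.3 in albino ones (-1.36 ± 0.21, adjusted p = 0.000550). Its relatives bHLH39 and bHLH101 rose by 2.67 and 2.84 in green, with bHLH101 the member not called in albino ones, and the iron signal peptides IMA1 and IMA3 by 2.34 and 2.11. The iron transporter IRT1 and the reductase FRO2, which take up iron in roots, did not pass in green (0.78 ± 0.26, adjusted p = 0.0994 and 0.79 ± 0.30, adjusted p = 0.156) and fell in albino seedlings (-2.58 and -2.96). The ferritins FER3 and FER4 and the vacuolar transporter VTL1 fell in green seedlings (-1.2, -1.41 and -1.16), and all 5 iron-storage genes were lower in both mutant groups.

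Copper-regulated genes moved in albino seedlings, and some of them also in green ones. The copper transporter COPT2 fell by 2.49 ± 0.15 (adjusted p = 3.09e-06), and YSL2 and FRO4 had -1.04 and -0.96. FRO4 was weakly expressed, at 1.82 ± 0.506 in the wild type and 0.435 ± 0.0561 in albino seedlings. CCS, the chaperone that delivers copper to superoxide dismutase, rose by 1.53 ± 0.15 (adjusted p = 3.08e-05) and the plantacyanin ARPN by 2.36 ± 0.22 (adjusted p = 2.41e-05). In green seedlings ZIP2 (-0.72, adjusted p = 0.00362) and FRO4 (-0.73, adjusted p = 0.0194) were lower and ARPN was higher (0.99, adjusted p = 0.0206). COPT1, COPT2, YSL2 and CCS did not pass there.

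An iron-deficiency type response in green seedlings may explain the first pattern. Of 12 iron-deficiency genes not looked at before, 7 were higher in green and 0 lower (11 and 0 adjusted over the list alone). Among them were IMA2 (2.28) and NAS4 (2.02), as such a response would give. These genes belong to the same response as those already seen, so they are not an independent test. In albino seedlings 7 of these 12 were lower and 1 higher, NAS4 (0.80 ± 0.17, adjusted p = 0.00341), so the albino side holds for only part of them. The 5 iron-storage genes were lower in both mutant groups, and 3 of them were lower in albino than in green seedlings. Storage genes thus did not move in opposite directions. Iron content of green and albino seedlings and a trial with added iron would test the explanation. More copper available to the shared copper regulators might explain the opposite calls of CSD1 and FSD1: 5 of 5 measured copper-deficiency genes not looked at before, COPT2, YSL2 and FRO4 among them, were lower in albino seedlings. In green seedlings 2 of the 5 were also lower (3 adjusted over the list alone) and FSD1 fell too, so the pattern is not limited to albino ones. The 5 genes belong to the same copper response as CSD1 and FSD1, so they are not an independent test. Over all 19731 genes tested, 3968 were lower in albino seedlings. Copper measurements would test the explanation. A weaker touch or wound response at harvest could explain the low WRKY40, RRTF1 and JAZ genes, and 9 of 10 measured touch and wound genes not looked at before were lower in albino seedlings, among them TCH4, a cell-wall enzyme (-2.53 ± 0.18, adjusted p = 6.00e-06). In green seedlings, where WRKY40 and JAZ5 were also lower, only 2 of the 10 were (5 adjusted over the list alone), so the explanation stays open there. The green call of WRKY40 was lost without wild-type replicates 1 or 3 or green replicates 1 or 2 (adjusted p from 0.0603 to 0.0779) and without a filter (0.0544), and that of JAZ5 without wild-type replicate 3 (0.0517). The 10 touch and wound genes were likewise chosen from the response that the low genes had pointed to, so they are not an independent test. Harvests timed after a set touch would test the explanation by touch.

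Some zeros in the table came with overlapping genes. A log2 value above 3 in a library and 0 in another of the same group was found for 55 genes, of which 46 were tested and 45 of these had a reference position. Of the 45, 43 (95.6%) overlapped another gene, against 31.7% of other tested genes with a position (Fisher exact p = 1.82e-19). The long noncoding RNA AT1G09927 is of this kind and lies antisense to PRPS17.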
